A study of Mus musculus with 47 samples.

How the data were processed

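Polyadenylated RNA was measured by paired-end sequencing in 47 samples of mouse kidney, which the labels name as metanephros and the series title as kidney. The reads were 100 bp long and the target was 30 M (M, mega) read pairs per library, per the labels' protocols. The labels also state that spike-in RNA was added before library construction, but the deposited tables hold no spike-in rows, so no spike-in scaling was possible.

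The authors deposited a table of expected counts per gene for 22474 genes, of which 21% of the values were not whole numbers. Neither the file headers nor the labels state the aligner or the counting tool. The genome build was GRCm38, per the submitters' processing notes, and the same notes name DESeq2 without a version. The authors also deposited a variance-stabilized matrix of the same genes and samples on a log2 scale, with values from 5.93 to 21.1. Gene symbols, identifiers and coordinates came from the deposited annotation table, whose coordinates in megabases were multiplied out to bases.

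Expected counts were rounded to whole numbers. Genes were kept with edgeR's filterByExpr over the 12 groups of strain, sex and diet, which left 18786 genes and set aside 3688. Library sizes were scaled by TMM. edgeR 4.0.16 in R 4.3.3 fitted a robust quasi-likelihood model with a mean per group and an additive term for the 3 runs of sample ID numbers, leaving 33 residual degrees of freedom. The labels do not say what these runs are. Contrasts of group means were tested with the quasi-likelihood F test, and Benjamini-Hochberg adjusted p under 0.05 was the threshold in every comparison. All adjusted p-values of genes come from this test unless another is named. Standard errors of log2 fold changes were derived from the F statistic. Expression values are CPM, computed from the deposited counts with TMM-scaled library sizes.

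The contrasts were 44% against 10% fat within each strain as the mean of both sexes, the differences of these diet effects between strains and between sexes, females against males within each strain, and the strains against each other on 10% fat. Principal components were computed from log2 CPM with a prior count of 1 over 7657 genes with an average log2 CPM above 4. The genes named follow a rule fixed before the data were examined. A candidate had an adjusted p under 0.05, an average log2 CPM of at least 1, a mean of at least 10 counts per library in each cell of its contrast, and a symbol that is not a predicted or clone name. The 10 highest and 10 lowest log2 fold changes could be named for diet contrasts and the 5 highest and 5 lowest for other contrasts. From each fixed gene list that is described, up to 4 members with the smallest adjusted p could be named, passing or not, and sex chromosome genes served as a check of the labels. Ace, Fasn, Slc2a2 and Slc5a2 in some diet contrasts, and Pvalb between strains, are named without a description of a list that holds them. Other genes named outside this rule are identified as chosen after their values were seen.

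37 gene lists of kidney cell types, immune cells, metabolism, stress, injury and sex were fixed before the data were examined. Each was tested in each contrast with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists of the contrast. Camera with an estimated correlation and fry were run beside it. Members were also counted when adjusted over the list alone.

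The alternatives were DESeq2's median-of-ratios size factors in edgeR, no expression filter, the Wald test of DESeq2 1.42.0, limma-voom with sample quality weights, no ID run term, limma on the deposited variance-stabilized matrix, a fit with only the samples of the strains compared, and leaving out each library in turn. For each count of called genes, 40 random regroupings and the real one were compared. The label order was shuffled within the cells that the contrast does not compare. The model was tested on simulated counts with 50 genes changed at each of 4 folds per strain. In the simulated diet comparison of C57BL/6J it recovered 68% of the genes changed 1.25-fold and 94% of those changed 1.5-fold. For CAST/EiJ it recovered 66% and 84%, and for NZO/HlLtJ 60% and 94%. For the difference of diet effects between NZO/HlLtJ and C57BL/6J it recovered 32% and 90%. Unchanged genes made up 2.16% to 5.43% of the calls. The simulation differed from the data. Changed genes had an average log2 CPM of at least 1, and counts were drawn independently per gene with the fitted spread. In C57BL/6J 185 simulated genes were called where the real data gave 5, so the adjusted threshold was looser. Recovery on the real counts may therefore be lower. After the values were seen, diet contrasts were also fitted without each ID run and the called genes looked up in the run left out, and library composition was compared between diets by exact permutation tests. Shared sequence between genes was measured as 31-mers of the GENCODE M21 transcripts with Python 3.11.15 and scipy 1.17.1, and plots were drawn with matplotlib 3.10.9.

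Totals per library ran from 34.4 M to 58.4 M counts. With 12724 genes at an average log2 CPM of at least 1, the median standard error of a log2 fold change was 0.062 for diet in C57BL/6J, 0.066 in CAST/EiJ and 0.062 in NZO/HlLtJ. No sample was left out.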

Results

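The data were 47 RNA-seq libraries from mouse kidney. They came from 3 inbred strains, C57BL/6J, CAST/EiJ and NZO/HlLtJ, in both sexes, on a diet with 10% fat and fiber or a diet with 44% fat and fiber. The series description calls the diets a control diet and a high fat, high sugar diet, and its title asks how genotype and diet interact in mouse models of type 2 diabetes. Mice were placed on a diet at 6 weeks of age and tissue was collected at 15 weeks. Of the 12 groups of strain, sex and diet, 11 held 4 libraries and 1, CAST/EiJ males on 10% fat, held 3. The total count per library ran from 34.4 M to 58.4 M counts (M, mega) with a median of 44.8 M. Mitochondrial genes took 10.7% to 15.5% of the counts and the 10 highest genes 14.1% to 18.9%. In the males measured, the mitochondrial share differed between the diets, in different directions by strain, though not at an adjusted p under 0.05. In NZO/HlLtJ males it was 12.24% to 14.27% on 44% fat and 10.69% to 11.95% on 10% fat, in C57BL/6J males 14.36% to 15.46% and 13.1% to 13.84%, and in CAST/EiJ males 11.13% to 12.64% and 13.33% to 14.07%. Each of these differences had a 2-sided exact permutation p of 0.0286, the smallest such groups allow, and 0.0572 adjusted over 6 groups of strain and sex. In NZO/HlLtJ females the adjusted p of the same exact test was 0.0856. The 10 highest genes took 17.47% to 18.88% in NZO/HlLtJ males on 44% fat and 15.44% to 16.67% on 10% fat. CAST/EiJ males went the other way, with 14.84% to 16.89% and 17.08% to 17.9%. In both groups the exact permutation p adjusted over 6 groups was 0.171. None of these adjusted p-values was under 0.05, and the exact tests took no account of the ID runs. In the values measured, library composition and diet were still not separate in the males of these groups. The labels do not state that each library is a separate animal, so the p-values measure the spread between these samples.

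The sample ID numbers fall in 3 runs, 77, 81 and 89, of 16, 16 and 15 libraries. Of 18786 genes, edgeR called 0 for a difference between the runs. An unadjusted p under 0.05 was found for 1258, where 939 would be expected by chance. No other tool tested this term. In runs 81 and 89 the NZO/HlLtJ females were on one diet and the males on the other, so a diet effect in this strain could be estimated within run 77 alone. Xist lay at 863 CPM or more in each of 24 female libraries and at 2.43 CPM or less in each of 23 male libraries, and Ddx3y at 0.0702 CPM or less in females and 48.6 CPM or more in males, so the sex labels fitted the data.

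The first component of log2 CPM held 39.1% of the variance, the second 36.0% and the third 10.4%. Strain and sex together accounted for 99.4% of the variation along the first and 99.6% along the second. Diet accounted for 0.0126% along the first and 0.125% along the second. Along the sixth component, which held 1.47% of the variance, diet accounted for 30.9% and the ID run for 15.2%.

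**Figure D1:**
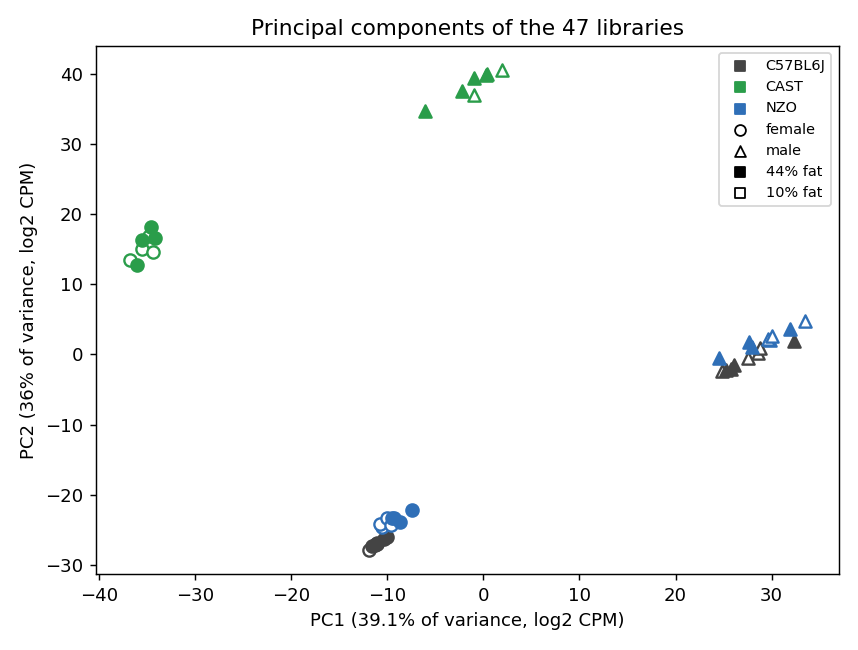
Each point is 1 of the 47 libraries on the first 2 principal components of log2 CPM, coloured by strain, shaped by sex and filled for 44% fat. The libraries fall by sex within each strain, with CAST/EiJ apart from the other strains. The males of those other strains intermix, and diet does not separate the libraries on these axes.

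In C57BL/6J, 5 genes differed between the diets, 4 higher and 1 lower on 44% fat, and 1085 genes had an unadjusted p under 0.05 where 939 would be expected by chance. Col27a1 (ENSMUSG00000045672, GRCm38 chromosome 4, 63214004 to 63334991) rose by a log2 fold change of 0.65 (SE 0.11, adjusted p 0.0158). Its mean was 111 ± 7.13 CPM (SD, n = 4) in females on 44% fat and 69.4 ± 8.02 CPM (SD, n = 4) in females on 10% fat. In males it was 104 ± 24.7 CPM (SD, n = 4) and 67.4 ± 10.4 CPM (SD, n = 4). Aldh1a1 rose by 0.56 (SE 0.10, adjusted p 0.0158), and Slc5a10, a sugar transporter gene, by 0.47 (SE 0.09, adjusted p 0.0438). Slc5a10 measured 366 ± 81 CPM (SD, n = 4) on 44% and 232 ± 20.4 CPM (SD, n = 4) on 10% fat in females, and 205 ± 25.3 CPM and 165 ± 21.7 CPM (SD, n = 4) in males. Mmp12 rose by 1.07 (SE 0.21) and Col5a2 had a log2 fold change of -0.52 (SE 0.10), both at an adjusted p of 0.0438. These calls depended on single libraries. Col27a1 and Aldh1a1 were called in 12 of 16 fits with 1 library left out, and both lost their call without replicate 1 of females on 10% fat, replicates 1 and 3 of males on 10% fat or replicate 4 of males on 44% fat. Slc5a10 and Col5a2 were each called in 5 of those 16 fits and Mmp12 in 4. The count was 0 without any of the 4 libraries just named, 2 without replicates 3 or 4 of females on 10% fat, replicates 1 or 3 of females on 44% fat, replicate 4 of males on 10% fat or replicate 3 of males on 44% fat, and 13 without replicate 4 of females on 44% fat. In run 77 each C57BL/6J group held 1 library, and runs 81 and 89 also held such groups. Calls within a run therefore do not measure the spread in this strain and are not given. With run 81 left out 1 gene was called, and its sign in run 81 was the opposite. Among 15 genes of glucose transport and gluconeogenesis, 12 had a positive log2 fold change, 1 was called over all genes and 6 when adjusted over the list alone, with a median of 0.16. Camera gave this list an adjusted p of 3.15e-09, and 0.144 with an estimated correlation.

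In CAST/EiJ, 186 genes differed between the diets, 102 higher and 84 lower on 44% fat. The highest log2 fold change among the named genes was that of Havcr1 (ENSMUSG00000040405, chromosome 11, 46735080 to 46779578), which encodes kidney injury molecule 1, at 2.02 (SE 0.35, adjusted p 0.00286). Havcr1 measured 6.08 ± 5.38 CPM (SD, n = 4) in females on 44% fat and 1.18 ± 0.558 CPM (SD, n = 4) on 10% fat. In males it measured 10.4 ± 6.23 CPM (SD, n = 4) and 2.78 ± 0.652 CPM (SD, n = 3). Clu (chromosome 14, 65968483 to 65981548) rose by 1.19 (SE 0.17, adjusted p 0.000119), from 54.8 ± 3.09 to 149 ± 111 CPM in females and from 34.6 ± 3.85 to 68.7 ± 16.1 CPM in males. Both genes stayed called in each of the 15 fits that left out 1 library, and both lost their call in a fit of the CAST/EiJ samples alone. The rise of Havcr1 lay in runs 77 and 81. In run 89 it measured 1.84 CPM in the female library on 44% fat and 0.528 and 1.77 CPM in those on 10% fat, and 2.36 and 2.13 CPM in the male libraries, while Clu measured 113 CPM against 50.2 and 56.3 CPM in females and 54.6 against 30.2 CPM in males. Pvalb rose by 1.08 (SE 0.19, adjusted p 0.00186) at a mean of 1.26 CPM on 44% fat and 0.579 CPM on 10% fat. Cpne4 had a log2 fold change of -0.73 (SE 0.11, adjusted p 0.000119), Nlrp6 of -0.57 (SE 0.10, adjusted p 0.00186) and Fasn of -0.55 (SE 0.10, adjusted p 0.00452). Acaca (-0.29), Acacb (-0.19) and Scd1 (-0.35), also fatty acid synthesis genes, were not called. Of Pvalb, Cpne4, Nlrp6 and Fasn, Cpne4 alone stayed called with the CAST/EiJ samples alone. The sodium-glucose transporter gene Slc5a2 had a log2 fold change of -0.23 (SE 0.05, adjusted p 0.0239), and that call was lost in 5 of the 15 fits, those without replicate 3 of females on 10% fat, replicate 4 of females on 44% fat, replicates 1 or 2 of males on 10% fat or replicate 1 of males on 44% fat.

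Of 31 PPAR alpha targets and fatty acid oxidation genes, 29 had a positive log2 fold change in CAST/EiJ. Over all genes 8 were called higher and none lower, and adjusted over the list alone 14 were higher. Camera gave an adjusted p of 2.24e-17, and 0.276 with an estimated correlation. The 4 with the smallest adjusted p were Ucp2 at 0.33 (SE 0.07), Acaa1b at 0.58 (SE 0.12), Eci1 at 0.34 (SE 0.07) and Plin2 at 0.41 (SE 0.09). Ucp2 stayed called without each library, while Acaa1b lost its call without replicate 2 of males on 10% fat, Plin2 without replicate 1 of those males and Eci1 without either. Plin2 also lost its call with the CAST/EiJ samples alone. Of 20 tubular injury genes, 3 were called higher, Clu, Havcr1 and Tnfrsf12a, and 7 when adjusted over the list alone. Tnfrsf12a lost its call without replicate 4 of females on 10% fat, replicate 4 of females on 44% fat, replicates 1 or 2 of males on 10% fat or replicates 1 or 2 of males on 44% fat. It also lost it with the CAST/EiJ samples alone. Of 11 macrophage markers, all 11 had a positive log2 fold change with a median of 0.35, none was called over all genes and 5 when adjusted over the list alone. Camera gave the macrophage list an adjusted p of 7.02e-07, and 0.276 with an estimated correlation.

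The count in CAST/EiJ changed by more than 1.5 times without any of 8 libraries. It was 330 without replicate 2 and 94 without replicate 4 of females on 10% fat, 301 without replicate 1 and 85 without replicate 4 of females on 44% fat, 70 without replicate 1 and 57 without replicate 2 of males on 10% fat, and 117 without replicate 1 and 90 without replicate 2 of males on 44% fat. In run 77 each CAST/EiJ group held 1 library, and runs 81 and 89 also held such groups, so calls within a run are not given. Genes called without a run were looked up in that run for their sign alone, a test chosen after the values were seen. Of 54 genes called without run 77, 85.2% had the same sign within it, of 37 called without run 81 94.6%, and of 27 called without run 89 81.5%. Over all genes these shares were 57.4%, 58.4% and 58.8%.

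In NZO/HlLtJ, 680 genes differed between the diets, 372 higher and 308 lower on 44% fat. Mogat2 (ENSMUSG00000052396, chromosome 7, 99219084 to 99238619) rose by 1.16 (SE 0.15, adjusted p 2.41e-05), from 7.72 ± 1.88 to 13.6 ± 2.70 CPM (SD, n = 4) in females and from 7.37 ± 1.08 to 20.8 ± 4.32 CPM (SD, n = 4) in males. Cyp4a14 rose by 1.96 (SE 0.38, adjusted p 0.00286), from 422 ± 76.9 to 519 ± 71.1 CPM in females and from 1.07 ± 0.272 to 12.9 ± 10.5 CPM in males. Grem1 rose by 2.52 (SE 0.48, adjusted p 0.00182) and C3 by 0.84 (SE 0.18, adjusted p 0.00755). The lipoprotein lipase gene Lpl had a log2 fold change of -0.93 (SE 0.22, adjusted p 0.0138), from 774 ± 92.7 to 364 ± 90.7 CPM in females and from 414 ± 81.4 to 242 ± 74.7 CPM in males. Slc22a26 stood at -1.09 (SE 0.22), Zfp239 at -1.01 (SE 0.16) and Socs2 at -0.90 (SE 0.21). The genes named in this paragraph stayed called in each of the 16 fits that left out 1 library. Grem1 and Cyp4a14 lost their call with limma-voom, and Grem1 and C3 in a fit of the NZO/HlLtJ samples alone. The count was 448 without replicate 4 of females on 10% fat, 319 without replicate 1 and 401 without replicate 4 of males on 44% fat, and within 1.5 times of 680 without each other library. Within run 77 alone 16 genes were called. Of 60 genes called from runs 81 and 89 together, 93.3% had the same sign within run 77, against 61.5% over all genes.

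Among 15 glucose transport and gluconeogenesis genes in NZO/HlLtJ, 5 were called higher and none lower, and 9 were higher and 1 lower when adjusted over the list alone. Slc2a2, the gene of glucose transporter 2, rose by 0.50 (SE 0.08, adjusted p 0.000327), Slc5a10 by 0.56 (SE 0.09) and Pck1 by 0.62 (SE 0.12). Camera gave an adjusted p of 3.21e-09, and 0.0785 with an estimated correlation. All 10 intercalated cell markers had a negative log2 fold change with a median of -0.23. Of these 4 were called, Slc4a1 at -0.29 (SE 0.05), Slc4a9 at -0.27 (SE 0.06), Atp6v1g3 at -0.25 (SE 0.06) and Insrr at -0.27 (SE 0.06), and 8 were called when adjusted over the list alone. Insrr lost its call without replicate 1 of males on 44% fat. Camera gave this list an adjusted p of 3.21e-09, and 0.0354 with an estimated correlation, the only list of a diet contrast under 0.05 with an estimated correlation. Of 31 PPAR alpha and fatty acid oxidation genes 8 were higher and 1, Acadm, lower, with Plin2 at 0.54 (SE 0.09). Of 17 fatty acid synthesis genes 4 were lower, Fads1 at -0.40 (SE 0.05), Fads2 at -0.25 (SE 0.04), Scd1 at -0.75 (SE 0.15) and Srebf1 at -0.50 (SE 0.13), and 1, Gpam, was higher. Acadm and Gpam were chosen after their values were seen, and were called in 14 and 10 of 16 fits with 1 library left out. Srebf1 lost its call without replicates 1 or 4 of females on 10% fat, replicates 3 or 4 of females on 44% fat, replicates 2 or 3 of males on 10% fat or replicates 1 or 4 of males on 44% fat. The angiotensin-converting enzyme gene Ace had a log2 fold change of -0.51 (SE 0.07, adjusted p 6.03e-05), from 280 ± 56.5 to 194 ± 29.7 CPM (SD, n = 8). Of 14 cell cycle genes all 14 had a positive value with a median of 0.76, 3 were called, Birc5, Aurkb and Ccnb1, and 11 when adjusted over the list alone. Of 16 fits with 1 library left out, Birc5 was called in 15, Aurkb in 7 and Ccnb1 in 6. Without replicate 1 of males on 44% fat, or with the NZO/HlLtJ samples alone, none of these 3 was. Camera gave that list an adjusted p of 1.32e-07, and 0.415 with an estimated correlation.

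**Figure D2:**
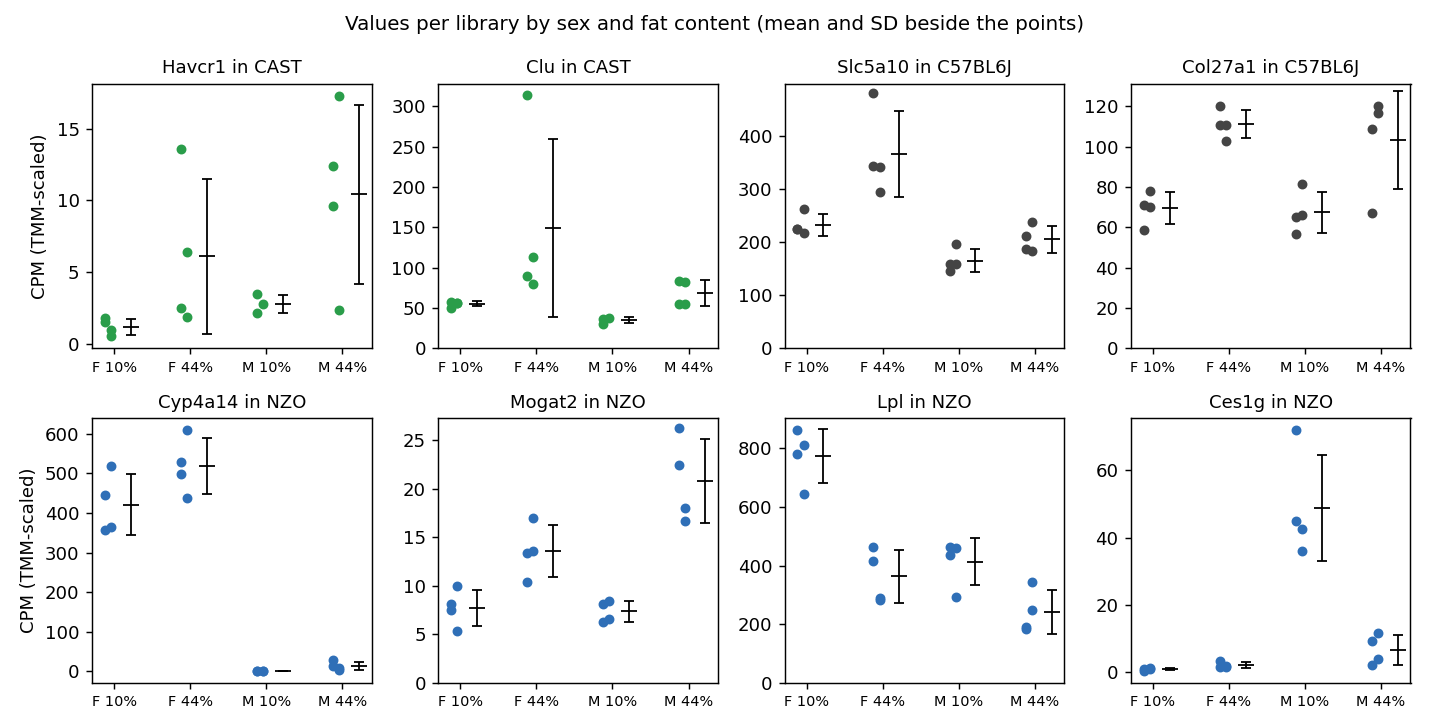
CPM per library of 8 genes named in the text, each in 1 strain, by sex and fat content, with the group mean and SD beside the points. Havcr1 and Clu in CAST/EiJ have 1 or more high libraries on 44% fat, while Lpl and Ces1g fall and Mogat2 rises in NZO/HlLtJ males.

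The strains share no library, but their diet lists came from the same fit, with a shared filter, run term and estimate of the spread. Fisher's exact test also treats genes as independent. Its p-values therefore describe the overlaps and do not test independent lists. Of the genes higher on 44% fat, 15 were shared by CAST/EiJ and NZO/HlLtJ where 2.02 would be expected of independent lists (Fisher's exact test, p 1.56e-09). They included Plin2, Eci1, Vnn1, Cyp4a10, Slc5a10 and Cxcl16, chosen after their values were seen. Of these, Cyp4a10 was called in CAST/EiJ in 4 of 15 fits with 1 library left out. Of the genes lower on 44% fat 2 were shared where 1.38 would be expected (Fisher's exact test, p 0.402). The shared count fell to 8 without replicate 4 of CAST/EiJ females on 10% fat or without replicate 1 of CAST/EiJ males on 10% fat, and to 7 without replicate 2 of those males. C57BL/6J and NZO/HlLtJ shared 3 higher genes, Slc5a10, Col27a1 and Aldh1a1, where 0.0792 would be expected (Fisher's exact test, p 3.04e-05). The C57BL/6J list behind this overlap fell to 0 genes in some fits with 1 library left out and in the fit of that strain alone. Slc5a10 was called in all 3 strains. In C57BL/6J it was called in 5 of 16 fits with 1 library left out. There it also lost its call without the filter, without the run term, on the deposited variance-stabilized matrix and with that strain's samples alone. Of the 680 genes called in NZO/HlLtJ, 82.8% had the same sign in C57BL/6J and 58.7% in CAST/EiJ, a comparison across genes, which are not independent replicates. The median ratio of the log2 fold change in C57BL/6J to that in NZO/HlLtJ over these genes was 0.25. Over all genes the Pearson correlation of the diet effects of NZO/HlLtJ was 0.12 with C57BL/6J and 0.10 with CAST/EiJ. Whether library composition contributed to the shared signs was not tested.

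**Figure D3:**
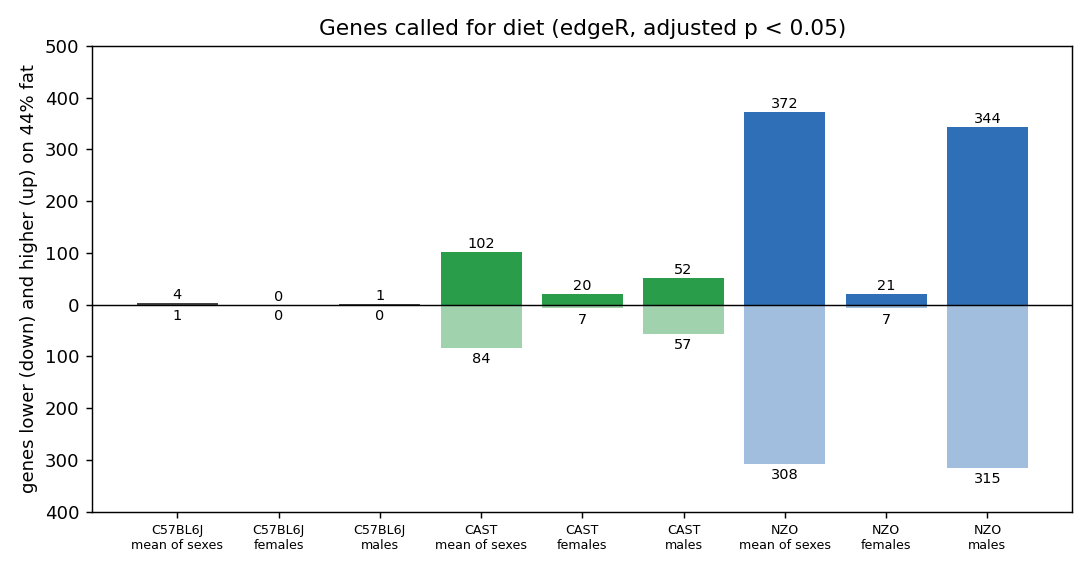
Bars give the number of genes higher (up) and lower (down, paler) on 44% fat in edgeR at an adjusted p under 0.05, per strain for the mean of both sexes and for each sex. Males of NZO/HlLtJ have 344 higher and 315 lower, females of that strain 21 and 7. Within a sex of this strain, diet went partly with the ID run.

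The differences of the diet effects between strains were tested directly, which is the interaction named in the series title. Between NZO/HlLtJ and CAST/EiJ 241 genes differed, 138 with a higher and 103 with a lower diet effect in NZO/HlLtJ. Ace differed by -0.73 (SE 0.11, adjusted p 0.000204), with a log2 fold change of 0.21 (SE 0.08) in CAST/EiJ. Slc2a2 differed by 0.62 (SE 0.12, adjusted p 0.00608) and Slc5a2 by 0.34 (SE 0.07, adjusted p 0.0138). Havcr1 differed by -2.14 (SE 0.48, adjusted p 0.0211). These 4 genes stayed called in each of the 31 fits that left out 1 library, and Havcr1 and Slc5a2 lost their call in a fit of the samples of these strains alone. Gprin3 differed by 1.01 (SE 0.18), Mansc4 by 0.97 (SE 0.17), Serpina1b by -1.28 (SE 0.26) and Azgp1 by -1.25 (SE 0.22). The count was 145 without replicate 4 of CAST/EiJ females on 10% fat, 120 without replicate 4 of CAST/EiJ females on 44% fat, 136 without replicate 1 of CAST/EiJ males on 10% fat and 124 without replicate 2 of CAST/EiJ males on 44% fat. In NZO/HlLtJ it was 155 without replicate 4 of females on 10% fat, 157 and 150 without replicates 1 and 3 of females on 44% fat, and 113 and 112 without replicates 1 and 4 of males on 44% fat.

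Between NZO/HlLtJ and C57BL/6J 7 genes had different diet effects, 3 higher and 4 lower, and under median-of-ratios scaling 3 did, 0 higher and 3 lower. Ace differed by -0.57 (SE 0.10, adjusted p 0.0428), Napsa by -0.40 (SE 0.08) and Fads2 by -0.30 (SE 0.06). The count was 0 to 21 in 32 fits with 1 library left out and stayed within 1.5 times of 7 in 4 of them. Ace was called in 16 of these fits and lost its call without each of the 16 libraries whose omission gave a count of 0. Napsa was called in 11 and Fads2 in 7. In C57BL/6J it was 0 without replicates 1, 3 or 4 of females on 10% fat, replicates 2, 3 or 4 of females on 44% fat or replicates 1, 2 or 4 of males on 10% fat, 1 without replicate 1, 3 without replicate 2 and 2 without replicate 4 of males on 44% fat, 3 without replicate 2 of females on 10% fat and 4 without replicate 1 of females on 44% fat. In NZO/HlLtJ it was 0 without replicates 2 or 4 of females on 10% fat, replicates 2 or 3 of females on 44% fat, replicate 1 of males on 10% fat or replicates 1 or 4 of males on 44% fat, 3 without replicate 1 and 1 without replicate 3 of females on 10% fat, 2 without replicate 4 of females on 44% fat, 2, 4 and 19 without replicates 2, 3 and 4 of males on 10% fat, and 21 without replicate 3 of males on 44% fat.

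Between CAST/EiJ and C57BL/6J 10 genes had different diet effects, 6 higher and 4 lower. Havcr1 differed by 2.45 (SE 0.49, adjusted p 0.0363), Clu by 1.19 (SE 0.22, adjusted p 0.0347) and Inmt by -1.42 (SE 0.29, adjusted p 0.0441). Havcr1 was called in 11 and Clu in 19 of 31 fits with 1 library left out. The count was 0 without replicates 1 or 4 of C57BL/6J females on 10% fat, replicate 3 of C57BL/6J females on 44% fat, replicate 2 of C57BL/6J males on 10% fat, replicate 4 of C57BL/6J males on 44% fat, replicates 1 or 2 of CAST/EiJ males on 10% fat or replicate 1 of CAST/EiJ males on 44% fat. It was 1 without replicate 1 of C57BL/6J females on 44% fat, replicate 4 of CAST/EiJ females on 10% fat or replicate 2 of CAST/EiJ males on 44% fat, 4 and 6 without replicates 3 and 4 of C57BL/6J males on 10% fat, 3 without replicate 4 of CAST/EiJ females on 44% fat, 20 without replicate 3 of CAST/EiJ males on 10% fat, and 21 and 18 without replicates 3 and 4 of CAST/EiJ males on 44% fat.

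Tested within each sex, diet changed 659 genes in NZO/HlLtJ males and 28 in NZO/HlLtJ females, 109 in CAST/EiJ males and 27 in CAST/EiJ females, and 1 in C57BL/6J males. In C57BL/6J females edgeR called 0 genes, with 702 at an unadjusted p under 0.05 where 939 would be expected by chance. No other tool was run within a sex. The difference between the sexes was a separate test, in which diet and run were linked in NZO/HlLtJ in the same way. In C57BL/6J it called 0 genes in edgeR, with 530 at an unadjusted p under 0.05 where 939 would be expected by chance. DESeq2 called 1 gene and limma-voom 0, and without replicate 1 of males on 44% fat edgeR called 1. In NZO/HlLtJ it called 1 gene, Ces1g, with a female minus male difference of 4.08 (SE 0.69, adjusted p 0.0191), while DESeq2 called 36, 13 higher and 23 lower, and limma-voom 2. Ces1g fell from 48.9 ± 15.9 to 6.57 ± 4.48 CPM (SD, n = 4) in males and rose from 0.782 ± 0.340 to 1.97 ± 0.808 CPM (SD, n = 4) in females. This call was lost without replicates 1 or 3 of females on 10% fat or replicate 1 of females on 44% fat, where the count was 0. The count was 2 without replicate 4 of females on 10% fat, replicate 2 of females on 44% fat or replicate 4 of males on 10% fat, and 5 and 4 without replicates 2 and 3 of males on 44% fat. Over the 659 genes called in NZO/HlLtJ males, 70.6% had the same sign in females, with a median ratio of 0.16. In CAST/EiJ 9 genes differed between the sexes in edgeR, 29 in DESeq2 and 17 in limma-voom, among them Slc10a1 at 2.23 (SE 0.45) and Slc22a8 at -0.88 (SE 0.16), which were called in 3 and 9 of 15 fits with 1 library left out. That count was 3 without replicates 3 or 4 of females on 10% fat, 18, 2 and 4 without replicates 1, 2 and 3 of females on 44% fat, 15, 0 and 4 without replicates 1, 2 and 3 of males on 10% fat, and 1 without replicates 1 or 2 of males on 44% fat.

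Females and males differed in 8991 genes in C57BL/6J, 8937 in CAST/EiJ and 9383 in NZO/HlLtJ. In the 3 strains 4721, 4446 and 4774 of these were higher in females and 4270, 4491 and 4609 in males. All 3 strains shared 2509 genes higher in females, where 284 would be expected of independent lists, and 2751 higher in males, where 250 would be expected. Slc7a13 measured 1.45 ± 0.773 CPM (SD, n = 8) in C57BL/6J females and 981 ± 82.6 CPM (SD, n = 8) in males. Ugt1a2 measured 804 ± 102 CPM in C57BL/6J females and 0.774 ± 0.422 CPM in males. Of 12 genes known to be higher in male kidney, 11 were higher in males in each strain and 1 was higher in females. Of 8 genes known to be higher in female kidney, 6 were higher in females in C57BL/6J, 4 in CAST/EiJ and 7 in NZO/HlLtJ. Igf2 was higher in females by 6.80 (SE 0.23) in C57BL/6J and 8.12 (SE 0.24) in NZO/HlLtJ, while in CAST/EiJ its mean was 1.95 CPM in females and 1.20 CPM in males. Whether the sex difference of Igf2 differs between strains was not tested. Podocyte markers were higher in females for 12 of 12 genes in C57BL/6J, 11 in CAST/EiJ and 11 in NZO/HlLtJ, where 1 was lower. Intercalated cell markers were higher in females for 10, 9 and 10 of 10 genes. With an estimated correlation camera gave the male list adjusted p-values of 4.57e-09, 2.2e-07 and 9.12e-09 in C57BL/6J, CAST/EiJ and NZO/HlLtJ. The podocyte and intercalated lists passed that version in NZO/HlLtJ, each at 0.0289.

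On 10% fat, 6930 genes differed between NZO/HlLtJ and C57BL/6J, 3498 higher and 3432 lower in NZO/HlLtJ. Between CAST/EiJ and C57BL/6J 11272 differed, 5696 higher and 5576 lower in CAST/EiJ, and between NZO/HlLtJ and CAST/EiJ 11104, 5487 higher and 5617 lower in NZO/HlLtJ. The complement gene Cfb was lower in NZO/HlLtJ by a log2 fold change of -6.03 (SE 0.12) against C57BL/6J, at 5.10 ± 0.663 CPM (SD, n = 8) against 343 ± 87.9 CPM (SD, n = 8), and C2, its neighbour on chromosome 17, by -3.83 (SE 0.11). Cfb shared 75.5% of its 31-mers with another annotated gene. The overlapping gene Gm20547, chosen after its value was seen, measured 0.0834 CPM in NZO/HlLtJ, so the sum of both was 5.18 CPM. Of 12 complement genes 9 were lower and 3 higher in NZO/HlLtJ than in C57BL/6J. Agt was lower by -4.82 (SE 0.17) in NZO/HlLtJ, and Cacna2d2 was higher by 5.58 (SE 0.13). In CAST/EiJ, 18 of 22 interferon response genes were lower than in C57BL/6J and 3 higher, with Ifi44 at -3.74 (SE 0.13) and Irgm1 at -3.10 (SE 0.11). Camera gave that list an adjusted p of 2.32e-07, and 0.66 with an estimated correlation. All 7 MHC class II genes were lower in CAST/EiJ and in NZO/HlLtJ than in C57BL/6J. Whether reads lost to variants against the reference lowered the MHC class II or interferon response genes was not tested. Pvalb was lower in CAST/EiJ by -4.35 (SE 0.15), and Pzp higher by 7.09 (SE 0.13). Several of the largest strain differences lay in genes with near-identical copies. Hba-a1 was higher in NZO/HlLtJ by 7.32 (SE 0.26) while its sum with Hba-a2 measured 703 CPM in NZO/HlLtJ and 726 CPM in C57BL/6J. Pgk1-rs7 was higher in NZO/HlLtJ by 6.90 (SE 0.24) while its sum with Pgk1 measured 489 and 471 CPM. Sums did not remove the strain difference in each pair. That of Cyp2a4 and Cyp2a5 in CAST/EiJ was 0.361 times, and that of Eno1b and Eno1 1.56 times, the sum in C57BL/6J. The copies were chosen after their values were seen.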

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

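The tests of the Havcr1 and Clu difference, of the sex-biased genes in NZO/HlLtJ males, of mt-Co2 and of the regrouped samples were chosen after the results were seen.

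In CAST/EiJ on 44% fat, Havcr1 and Clu, both members of the tubular injury list, were higher than on 10% fat, and both differed from C57BL/6J in the test of the difference. For that difference Havcr1 was called in 11 and Clu in 19 of 31 fits with 1 library left out. Both lost that call on the deposited variance-stabilized matrix and with the samples of these strains alone. The tables argue against a single outlying library. Replicate 1 of CAST/EiJ females on 44% fat measured 314 CPM of Clu while the other libraries of its group measured 79.4 to 113 CPM, yet both genes stayed called without each of the 15 CAST/EiJ libraries in turn, with log2 fold changes from 1.61 to 2.23 for Havcr1 and from 0.88 to 1.28 for Clu. An even rise of all immune cells as the whole source is argued against as well. Of 33 immune cell markers 29 had a positive log2 fold change and 0 were called in edgeR, and their median was 0.36 where Clu rose by 1.19. Among abundant markers Csf1r measured 118 CPM on 44% and 99.4 CPM on 10% fat, Lyz2 27.7 and 22.7 CPM, and Igkc 22.6 and 6.07 CPM, all 3 chosen after their values were seen. The log2 fold change of Igkc was 1.77 (SE 0.6), above that of Clu. A median over all markers cannot weigh a single immune cell type. Some rise of immune cells, or of a single type among them, thus stays open. In run 89 alone Havcr1 hardly differed, with 1.84 CPM on 44% fat and 0.528 and 1.77 CPM on 10% fat in females, and 2.36 and 2.13 CPM in males, so a dependence on the ID run stays open for Havcr1. The diet, which the design names, stays open too, and no biological mechanism was tested. Both genes lost their call when only the CAST/EiJ samples were fitted.

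In NZO/HlLtJ males on 44% fat, several genes moved toward their level in females. Of the 659 genes called there, 55 were strongly sex-biased and 43 of those (78.2%) moved toward the female side. A score over 240 female-high and 274 male-high genes was -3.04 ± 0.24 (SD, n = 4) on 44% fat and -3.30 ± 0.07 (SD, n = 4) on 10% fat. The 2-sided exact permutation p was 0.114, adjusted over 6 such tests to 0.342, where the smallest p of the 70 splits is 0.0286. This test took no account of the ID runs. Within run 77 the scores were -2.95 and -3.36 on 44% fat and -3.41 and -3.24 on 10% fat. The other males on 44% fat, at -2.79 and -3.05, were in run 81. Those on 10% fat, at -3.31 and -3.26, were in run 89. The shift was not particular to these males. In CAST/EiJ males the score differed by 0.27 as well (exact permutation p 0.171, adjusted 0.342). In NZO/HlLtJ females it differed by -0.10, toward the male side, at the smallest exact permutation p of 0.0286 (adjusted 0.172). A shift of sex-dependent expression with the diet therefore may or may not be present, and these 8 libraries do not decide it. Female tissue in the libraries was argued against by Xist. If female tissue had supplied the Cyp4a14 of these males, Xist would have reached 6.57 to 72.8 CPM, but it measured 0.153 to 0.416 CPM, at 0.469% to 2.33% of the level needed, and 0 of the 4 libraries came near that level.

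Among strain differences of at least 32-fold, shared sequence was frequent. Of 131 such genes, 69 (52.7%) shared at least 20% of their 31-mers with another gene, against 76 of 652 matched genes (11.7%, Fisher's exact test, p 2.37e-23). Reads shared between near-identical genes may thus account for part of these differences. For mt-Co2 this could be followed in detail. It measured 14.3 ± 2.79 CPM (SD, n = 7) in CAST/EiJ and 5330 ± 603 CPM (SD, n = 8) in C57BL/6J on 10% fat, while the nuclear pseudogene Gm13341, chosen after its values were seen, measured 4690 and 0.327 CPM. The sum of both in CAST/EiJ was 0.883 times that in C57BL/6J, so the reads of mt-Co2 in CAST/EiJ were likely counted under the pseudogene. Reads lost to variants against the reference would lower genes in CAST/EiJ. Of 99 genes that differed at least 32-fold between CAST/EiJ and C57BL/6J, 55 (55.6%) were lower in CAST/EiJ and 44 higher, which leaves that open. Differences of the strains' own genomes stay open and were not tested.

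Single libraries lay apart from the rest of their group in 8 of 63 groups tested, where 3.2 would be expected since chance sets apart about 1 in 20. Besides the Clu value above, replicate 1 of NZO/HlLtJ males on 44% fat had 51.46 M counts (others 39.38 to 41.41), and replicate 1 of C57BL/6J males on 44% fat had 15.46% mitochondrial counts (others 14.36% to 14.5%). Clu was 50.2 CPM in replicate 3 of CAST/EiJ females on 10% fat (others 55.8 to 56.8). Slc5a10 was 263 CPM in replicate 2 of C57BL/6J females on 10% fat (others 218 to 225), and Lpl 293 CPM in replicate 4 of NZO/HlLtJ males on 10% fat (others 436 to 465). Ces1g was 3.18 CPM in replicate 1 of NZO/HlLtJ females on 44% fat (others 1.52 to 1.66). The sex score was -3.85 in replicate 3 of C57BL/6J males on 44% fat (others -3.33 to -3.27).

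Diet effects that differed between strains or sexes are given as the difference of log2 fold changes. Between NZO/HlLtJ and C57BL/6J 7 genes differed, among them Epdr1 (0.54), Jak1 (0.21), Ace (-0.57), Napsa (-0.40), Fads2 (-0.30) and Stard3 (-0.29). They were called in 5 to 16 of 32 fits with 1 library left out. Between CAST/EiJ and C57BL/6J 10 differed, among them Havcr1 (2.45), Clu (1.19), Fancc (0.79), Fgf1 (0.60), Grk4 (0.56), Inmt (-1.42), Ces1e (-0.76), Abcd4 (-0.59) and Samd8 (-0.33), called in 7 to 23 of 31 such fits. Between NZO/HlLtJ and CAST/EiJ 241 differed, among them Gprin3 (1.01), Mansc4 (0.97), Snap91 (0.94), Cpeb3 (0.78), Ncam2 (0.78), Havcr1 (-2.14), Serpina1b (-1.28), Slc22a26 (-1.25), Azgp1 (-1.25) and Zfp239 (-1.19). Of 31 fits with 1 library left out, Slc22a26 was called in 6, Ncam2 in 16, Snap91 in 30 and the other 7 in each. Slc22a26 also lost its call without the filter, Ncam2 without the run term, and Slc22a26, Ncam2 and Havcr1 with the samples of these strains alone. Between females and males of CAST/EiJ 9 differed, among them Slc10a1 (2.23), Ugt2b38 (1.24), Slc22a8 (-0.88), Gsto1 (-0.69), Lzts2 (-0.53), Gstt3 (-0.53) and Scnn1b (-0.50), called in 3 to 14 of 15 such fits. In NZO/HlLtJ 1 gene did, Ces1g (4.08), called in 13 of 16.

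Each count was set against 41 regroupings of the samples, the real one included. For diet, the real grouping alone, 1 of 41, reached the count in CAST/EiJ (186, highest other 6) and NZO/HlLtJ (680, highest other 16), and for the difference between NZO/HlLtJ and CAST/EiJ (241, highest other 3). A share of 1 of 41 is the smallest these regroupings allow and was not adjusted over the contrasts. It argues against chance for these counts without excluding it. The regroupings were not balanced over the ID runs, so a diet difference linked to the run is not addressed. The share was also 1 of 41 for diet in C57BL/6J (5, highest other 1) and for the differences of CAST/EiJ and C57BL/6J (10, highest other 4) and of NZO/HlLtJ and C57BL/6J (7, highest other 6). These 3 small counts were 27, 47 and 22 in DESeq2 and 12, 26 and 10 in limma-voom. In edgeR they fell to 0 when 1 library was left out, for 4, 8 and 16 choices of that library, and to 0, 0 and 1 with only the samples of the strains compared, so they are not treated as beyond chance. For sex the share was 1 of 41 in C57BL/6J (8991, highest other 0), CAST/EiJ (8937, highest other 387) and NZO/HlLtJ (9383, highest other 2). It was also 1 of 41 for the strain contrasts of NZO/HlLtJ and C57BL/6J (6930, highest other 0), CAST/EiJ and C57BL/6J (11272, highest other 2) and NZO/HlLtJ and CAST/EiJ (11104, highest other 0). Shuffling sex or strain adds the real differences to the spread within groups, so low counts in the other groupings were likely beforehand. Where a real diet effect exists, shuffling diet does this too, which also favours low counts. Chance cannot be excluded for the sex differences of the diet effect. As many genes were reached by 4 of 41 in CAST/EiJ (9, highest other 28), by 10 of 41 in NZO/HlLtJ (1, highest other 345) and by 41 of 41 in C57BL/6J (0 in edgeR, 530 at an unadjusted p under 0.05, 1 in DESeq2, 0 in limma-voom, highest other 3). The regrouping that called 345 genes kept the real diet of 8 of 8 NZO/HlLtJ females and of 2 of 8 NZO/HlLtJ males. With most males exchanged, its female minus male difference mixed in the real diet effect. In CAST/EiJ the regrouping with 28 genes kept the diet of 7 of 7 males and of 2 of 8 females. Such regroupings are not free of a diet effect, so this comparison does not decide on chance for the sex differences. Other regroupings that kept 6 of 8 NZO/HlLtJ females and 2 of 8 NZO/HlLtJ males called 0 genes in edgeR, the one tool run on them. Whether the diet effect accounts for the 345 genes was not tested. The next highest count in NZO/HlLtJ, 22, came from a regrouping that followed the ID runs. It had the 4 NZO/HlLtJ females of run 77 on 44% fat and the 4 males of run 77 on 10% fat. Within run 77 the real grouping called 0 genes for this difference in edgeR, the one tool run within a run.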

How the results depend on the processing

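The alternatives for the overlap of the diet calls and for Acadm and Gpam were added after seeing the data, and the others were planned. No paired analysis was possible because the labels give no replicate numbers. The ID runs hold unequal numbers of libraries per group and entered the model as a term.

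Counts of called genes for sex and for strain stayed within 1.5 times under every alternative and without any library. Others moved, and the cause was not tested. With DESeq2 the count was 27 for diet in C57BL/6J, 432 in CAST/EiJ, 22 for the diet difference of NZO/HlLtJ and C57BL/6J, 47 for CAST/EiJ and C57BL/6J, 505 for NZO/HlLtJ and CAST/EiJ, 1, 29 and 36 for the sex difference of the diet effect in C57BL/6J, CAST/EiJ and NZO/HlLtJ, and 37 for the overlap of diet calls in CAST/EiJ and NZO/HlLtJ. With limma-voom it was 12 for diet in C57BL/6J, 501 in CAST/EiJ, 26 for CAST/EiJ and C57BL/6J, 474 for NZO/HlLtJ and CAST/EiJ, 17 and 2 for the sex difference in CAST/EiJ and NZO/HlLtJ, and 38 for the overlap.

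With only the samples of the strains compared, and so fewer samples, it was 0 for diet in C57BL/6J, 51 in CAST/EiJ, 254 in NZO/HlLtJ, 1, 0 and 62 for the strain differences in the order above, 0 for the sex difference in CAST/EiJ and 0 in NZO/HlLtJ, and 4 for the overlap. Without the filter, and so with more genes tested, it was 2 for diet in C57BL/6J, 0 for NZO/HlLtJ and C57BL/6J, 6 for CAST/EiJ and C57BL/6J and 5 for the sex difference in CAST/EiJ. On the deposited variance-stabilized matrix it was 1 for diet in C57BL/6J, 4 for NZO/HlLtJ and C57BL/6J, 4 for CAST/EiJ and C57BL/6J, and 18 and 2 for the sex difference in CAST/EiJ and NZO/HlLtJ. Without the ID run term it was 2 for diet in C57BL/6J, and with median-of-ratios scaling 3 for NZO/HlLtJ and C57BL/6J. Of the list tests 150 passed with the preset correlation and 11 with an estimated one. For diet in NZO/HlLtJ the fit of that strain alone had 111 genes higher and 143 lower, where the main fit had 372 and 308.

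Without each library in turn, diet counts ranged from 0 to 13 in C57BL/6J, 57 to 330 in CAST/EiJ and 319 to 1004 in NZO/HlLtJ. The strain differences ranged from 0 to 21, 0 to 21 and 112 to 343 in the order above, the sex differences of the diet effect from 0 to 1, 0 to 18 and 0 to 5, and the overlap from 7 to 20.

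For named genes, 2132 values under other settings kept their direction, 1960 with the same call, 152 no longer past the threshold and 20 newly past it. Of 5251 values without a library, 4558 had the same call, 674 were no longer past it and 19 newly past it, and 0 reversed. On simulated counts 60% to 68% of the genes with the smallest diet change simulated were recovered, so smaller diet effects could be missed.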

Other observations

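All values here belong to gene lists fixed with the others, and no explanation was tested for them. Markers of several nephron segments were higher in females than in males. For the thick ascending limb, 8 of 9 markers were higher in females in each strain, with median log2 fold changes of 0.42 in C57BL/6J, 0.36 in CAST/EiJ and 0.69 in NZO/HlLtJ. For the distal convoluted tubule it was 5, 5 and 6 of 7 markers. Proximal tubule markers went both ways, with 5 higher and 6 lower of 15 in C57BL/6J, 5 and 6 in CAST/EiJ and 4 and 7 in NZO/HlLtJ. Of 32 oxidative phosphorylation genes, 15, 21 and 22 were higher in males. With an estimated correlation, none of these 4 lists passed 0.05 in camera.

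In NZO/HlLtJ, the diet effect on B and plasma cell markers was higher in females than in males for 10 of 10 genes, with a median difference of 2.31. In edgeR 0 of them were called over all genes and 8 when adjusted over the list alone. Camera gave an adjusted p of 0.000177, and 0.594 with an estimated correlation. The values were uneven between libraries. Igkc, chosen after its values were seen, measured 2.23 to 136 CPM in the 4 NZO/HlLtJ females on 44% fat and 1.94 to 4.64 CPM in those on 10% fat.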
